A study of Mus musculus with 6 samples.

How the data were processed

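Gene expression was measured on 6 Affymetrix arrays in mouse bone marrow cells, 2 arrays for each of 3 groups: empty vector, Rad21 shRNA1 and Rad21 shRNA2. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, marrow of C57/BL6 mice aged 6 to 8 weeks was depleted of lineage-positive cells and exposed to lentivirus for 24 h. Puromycin at 1 µg/mL then selected infected cells, live cells were sorted, and 10000 cells per mL were plated in methylcellulose with cytokines, which the labels do not name. RNA was extracted with Trizol and column clean-up on day 7, at the end of this primary plating, and biotin-labelled for hybridization, per the labels' protocols.

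The deposited table holds 1 intensity value for each of 22690 probe sets on each array, made by the authors with RMA, per the submitters' processing notes. RMA corrects the background, quantile-normalizes the arrays and summarises the probes of a set on the log2 scale. Its version, the software, the array design's genome build and whether all 6 arrays were processed together are not given in the sources used here. The values ran from 4.96 to 20614.6 with array medians from 100.2 to 104.9, so they are on a linear scale. The test had been planned for log2 values, with log2 to be taken if they were linear, and log2 was taken. No pseudocount was added and no further normalization was applied. RMA pulls the distributions of all arrays together, so a change in total RNA per cell cannot be seen, and it compresses differences of dim probe sets.

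Probe sets were named through the platform annotation. Of the 22690, 20393 had 1 gene, 691 several and 1606 were not listed there. 64 Affymetrix control probe sets were kept out of the gene tests, 13 of which carried a gene name. They had first been left in by mistake and were removed after results had been seen, which changed no count of called genes. Of the 20380 probe sets used, 20351 had an Entrez number found in the RefSeq gene table of assembly GRCm38.p6, which was used for names only, and no symbol needed updating. A gene was represented by the probe set with the highest mean over the 6 arrays. This gave 12393 genes, 4956 of them with 2 or more probe sets. No gene was filtered out for low intensity.

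Differences were tested with limma (version 3.58.1, R 4.3.3), using lmFit and eBayes in a single fit of the 3 groups with 3 residual degrees of freedom and 2.91 prior ones. The contrasts were the mean of both shRNAs minus empty vector, each shRNA minus empty vector, and shRNA1 minus shRNA2. The last contrast is also the test of whether the effects of the 2 shRNAs differ. All tests were two-sided. Adjusted p-values are Benjamini-Hochberg values over all 12393 genes, with a threshold of 0.05. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

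Gene lists were written from general knowledge before the data were examined. They were cohesin subunits and regulators, the Hoxa cluster, stem and progenitor cell, Polycomb group, myeloid transcription factor, neutrophil, monocyte and macrophage, mast cell and basophil, eosinophil, erythroid, megakaryocyte, B cell, T and NK cell, dendritic cell and MHC class II, stromal and endothelial, DNA replication, mitosis, p53 target, interferon-stimulated, inflammatory NF-kB, Myc and nucleolar, cholesterol synthesis, integrated stress response, immediate early and heat shock, hypoxia and glycolysis, and sex-linked genes. These 26 lists had 563 entries, 488 of them with a probe set, and some genes stand in more than 1 list. Each list was compared with all other genes by limma's camera with a preset correlation of 0.01 between genes, and adjusted over the 26 lists. As alternatives, camera was run with the correlation estimated from the data, and fry was run, which asks whether a list moves on balance in 1 direction without comparing it with other genes. Members of a list were also adjusted over the list alone.

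The genes named in the text followed a rule set in advance. Rad21 and the Hoxa cluster were always named. For the mean of both shRNAs, the rule took the 12 largest rises and 12 largest falls past the threshold whose 4 shRNA arrays all lay on the same side of both empty-vector arrays, and for a single shRNA the 5 largest in each direction without overlap between the groups. Where no gene passed, the 5 with the smallest p in each direction were named. From each list the rule took up to 4 members past the threshold, or otherwise the 2 with the smallest p. All of these are named for the mean of both shRNAs, and only some of them for the other contrasts. Any gene named outside this rule is said to have been chosen after its values were seen.

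Alternatives fixed in advance were leaving out the dimmest 25% or the dimmer 50% of genes by mean intensity, the mean of all probe sets of a gene, quantile normalization of the deposited values, centring each array on its median, an intensity trend or robust settings in eBayes, a fit of only the groups compared, the replicate number as a block, each shRNA against a different empty-vector array, and leaving out each array in turn. When an array is left out, the lone array of its group is assumed to vary like the other groups. It adds nothing to the estimated spread, so the comparison of the other groups repeats the fit of only those groups. The empty-vector arrays lay further apart than those of either shRNA. Leaving out either of them therefore lowers the estimated spread and adds calls, and a call kept or gained there shows no stability.

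The replicate numbers come from the sample titles, which do not say what a number marks. Deviations of same-numbered arrays from their group means correlated across genes at 0.199 between empty vector and shRNA1, 0.148 between empty vector and shRNA2, and 0.578 between the shRNAs. All 3 lie above 0.1, and the numbers were read as pairing the arrays. The limit of 0.1 is no test, since with 2 arrays per group any shared axis of variation can give such values. The added poly-A controls were higher on replicate 1 than on replicate 2 in each group. Their means were 10.58 and 7.63 with empty vector, 8.72 and 7.46 with shRNA1, and 8.43 and 7.19 with shRNA2. What the numbers mark stays unknown. The reading as pairs was settled after the blocked results had been seen, so it was not blind to them. The results without the block are the reported ones, and an adjusted p with the block stands beside each result whose call it changes.

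Both shRNAs were compared with the same 2 empty-vector arrays, so their effects were also correlated over 100 draws of simulated unchanged groups sharing 2 controls, with 1 spread for all groups or a spread per group. The pipeline was tested on simulated data for the mean of both shRNAs over 12393 genes in 10 draws. It recovered 61.9% of genes changed by 1 log2 unit, 97% of those changed by 2 and 100% of those changed by 4, and 5.79% of its calls were false. A list shifted by 0.5 log2 units was called in 10 of 10 draws with the preset correlation and in 0 with an estimated one, and 2 calls of other lists arose over the 10 draws. The simulated genes were drawn independently of each other and with the same spread in all groups. The draws therefore do not show how either camera setting performs on genes that vary together, or with unequal spreads. No 2 arrays held the same values. The number of arrays limits the precision, and no coordinates are given because the build was not named.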

Results

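The series measured RNA in mouse bone marrow progenitors after knockdown of Rad21, a core subunit of cohesin, the ring complex that holds sister chromatids together and extrudes chromatin loops. Cells carried a lentivirus with no shRNA (empty vector) or with 1 of 2 shRNAs against Rad21, and were collected on day 7 of growth in methylcellulose, where progenitors form colonies of myeloid cells. Each of the 3 groups had 2 arrays, and their median intensities lay between 100.2 and 104.9. Differences below are shRNA minus empty vector on the log2 scale, ± the standard error of the limma fit, with n = 4 shRNA and 2 empty-vector arrays for both shRNAs together and n = 2 and 2 for a single shRNA. The labels do not say that replicates came from separate cultures or animals, so the p-values measure only the spread between these arrays, which may be technical.

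Empty-vector replicate 1 stood apart in its quality controls. The Gapdh 3′ control probe set lay 2.42 log2 units above the 5′ one on this array, against -0.078 to 0.017 on the other 5, and the Actb gap was 2.55 against 0.22 to 0.33. Its added poly-A control RNAs averaged 10.58, against 7.19 to 8.72 elsewhere. The 2 empty-vector arrays lay 0.321 (root mean square over genes) from their mean, compared with 0.151 for the shRNA1 and 0.141 for the shRNA2 arrays. The fit assumes 1 spread for all 3 groups. On average over genes, standard errors and p-values against empty vector are therefore likely too small, and those between the shRNAs too large. Erythroid genes averaged 8.76 on empty-vector replicate 1 and 6.92 to 7.27 on the others.

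**Figure D1:**
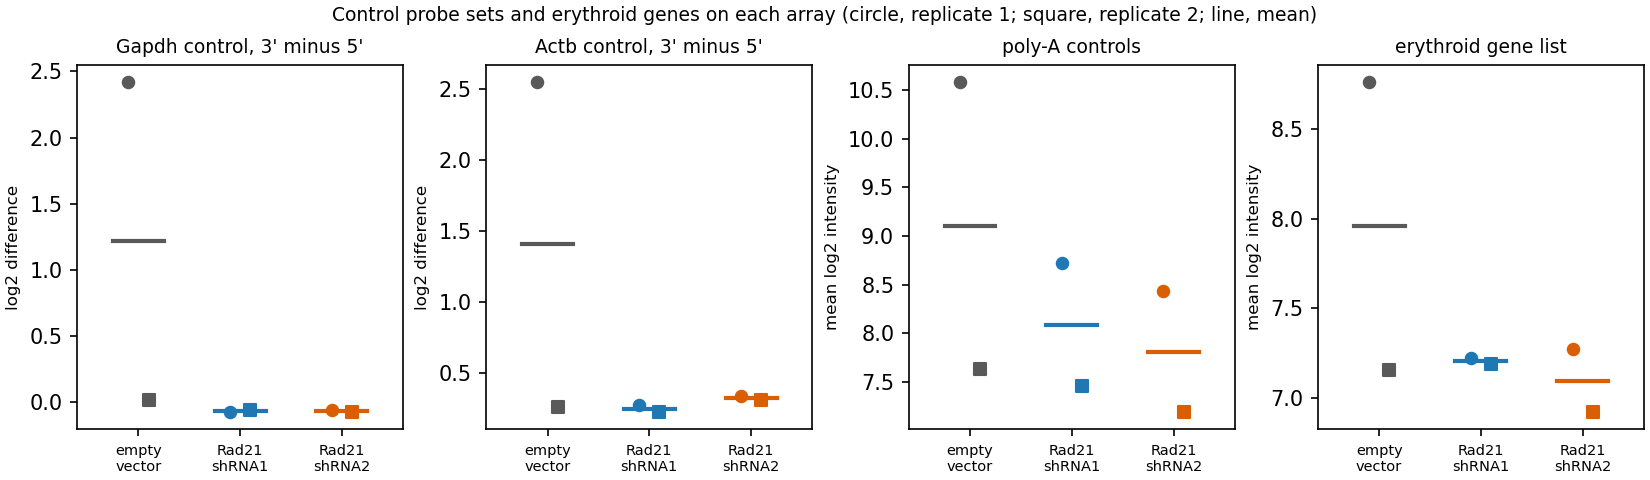
Control probe sets and the erythroid list mean (log2 units) on each of the 6 arrays. Empty-vector replicate 1 has a Gapdh 3′ minus 5′ gap of 2.42 and an erythroid mean of 8.76, above all other arrays.

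On its 2 brighter probe sets Rad21 was lower on every shRNA array than on either empty-vector array. The brightest stood at 125% and 79.8% of the empty-vector geometric mean on the 2 control arrays, at 43.8% and 31.2% with shRNA1 and at 40.2% and 30.6% with shRNA2. The mean over both shRNAs was 35.99% of control, a difference of -1.47 ± 0.26, which missed the threshold over all genes (limma adjusted p = 0.0558) and passed adjusted over the list alone (0.0105 among cohesin genes). With the replicate number as a block it passed at an adjusted p of 0.0166, so this call rests on how the replicate numbers are read. Leaving out empty-vector replicate 1 gave -1.15. Leaving out empty-vector replicate 2 gave -1.80, with only the array of the Gapdh gap of 2.42 as control. A range below is the lowest and highest adjusted p over all alternatives of a result, fits with an array left out included. For shRNA1 the difference was -1.44 ± 0.30 (adjusted p = 0.186; 0.0124 without empty-vector replicate 2, range 0.0124 to 0.805). For shRNA2 it was -1.51 ± 0.30 (adjusted p = 0.0644; 0.0166 with the block, 0.00913 without empty-vector replicate 2, range 0.00913 to 0.364). Of the other Rad21 probe sets, 1 bright one differed by -1.78 and a dimmer one by -0.43. On the dimmer one empty-vector replicate 1 (6.64) lay below replicate 1 of shRNA1 (6.86) and of shRNA2 (6.68).

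The first comparison asked which genes differed when Rad21 was targeted by either shRNA. The largest rise was in Mpo, encoding the granule enzyme myeloperoxidase, by 5.34 ± 0.49 (40.6-fold, adjusted p = 0.0124), followed by Csn2, the milk protein beta-casein, by 4.99 ± 0.23 (0.00318). The neutrophil serine proteases Elane and Prtn3 rose by 4.98 ± 0.21 and 4.93 ± 0.34 (adjusted p = 0.00293 and 0.00813), and Hoxa9, a homeobox gene of stem cells and myeloid leukaemia, by 3.29 ± 0.32 (0.0138). Rbp4, a retinol carrier, fell by 5.40 ± 0.78 (adjusted p = 0.0365), the collagenase Mmp13 fell by 4.30 ± 0.60 (0.0333) and the adhesion molecule Cdh1, or E-cadherin, fell by 3.86 ± 0.49 (0.0264). In each of these genes all 4 shRNA arrays lay beyond both empty-vector arrays, as the naming rule required.

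In all, 264 of 12393 genes passed, 91 rising and 173 falling, and 226 of them differed by more than 2-fold. Among genes past the threshold, the remaining largest rises were in Myl10 (4.17 ± 0.32), the granulocyte progenitor gene Ms4a3 (4.15 ± 0.60), Ambp (3.99 ± 0.40), the myeloid receptor Trem3 (3.47 ± 0.44), the transcription factor Tal2 (3.39 ± 0.23), Dmkn (3.32 ± 0.46) and Lbp, which binds lipopolysaccharide (3.24 ± 0.38), with adjusted p between 0.00813 and 0.0365. The remaining largest falls among them were in the growth factor receptor Fgfr1 (-3.77 ± 0.22), Plet1 (-3.75 ± 0.16), Mab21l1 (-3.68 ± 0.21), the desmosome gene Pkp2 (-3.24 ± 0.35), Cdh17 (-3.20 ± 0.24), the antiviral genes Ifit1 (-3.17 ± 0.30) and Rsad2 (-3.16 ± 0.48), the chemokine Ccl17 (-3.12 ± 0.41) and the fatty acid transporter Cd36 (-2.94 ± 0.34), with adjusted p between 0.00293 and 0.0411. The count of 264 was 649 without empty-vector replicate 1, 3121 without replicate 2, 17 and 93 without shRNA1 replicates 1 and 2, 3 and 29 without shRNA2 replicates 1 and 2, and 113 with the dimmer 50% of genes left out. The 24 genes named by size kept their direction with any array left out, and their calls in 24, 24, 8, 14, 3 and 11 cases in that order of arrays. The kept direction follows from the naming rule, which asked for arrays without overlap, and shows no stability. With the mean of all probe sets of a gene, Plet1 differed by -1.91, Fgfr1 by -2.43 and Pkp2 by -1.58, and Rsad2 missed the threshold with quantile normalization.

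**Figure D2:**
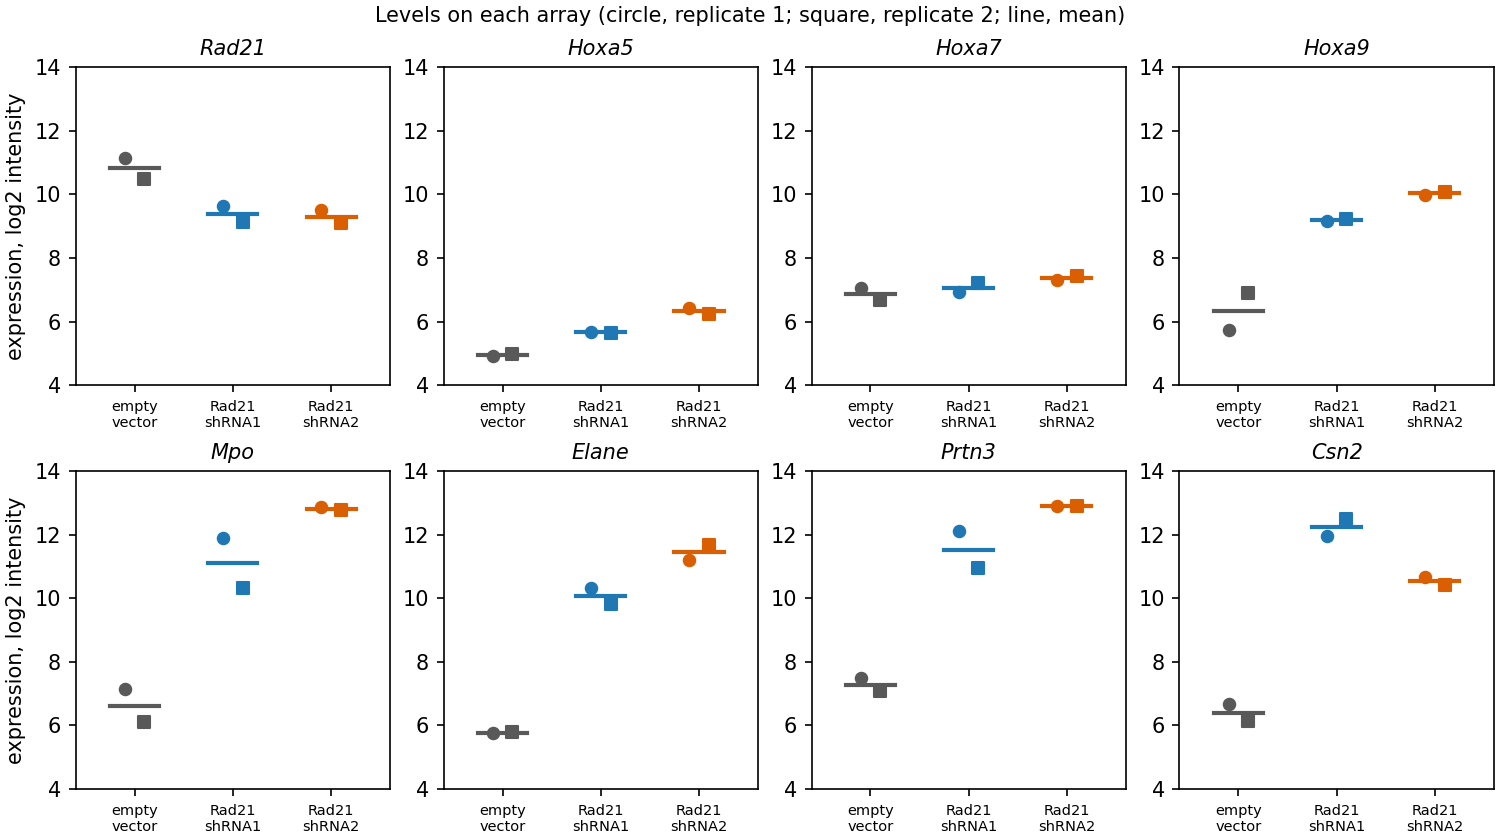
Log2 intensity of Rad21, Hoxa5, Hoxa7, Hoxa9, Mpo, Elane, Prtn3 and Csn2 on each array by group, with circles for replicate 1, squares for replicate 2 and a line at the group mean. Mpo averaged 6.62 with empty vector, 11.11 with shRNA1 and 12.81 with shRNA2.

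Neutrophil genes shifted upwards as a list, by a mean of 1.70. Of 21 measured, 7 rose over all genes tested and 12 adjusted over the list alone, led by Mpo, Elane, Prtn3 and Ms4a3 (camera adjusted p = 2.28e-09; adjusted p = 0.25 with an estimated correlation, range 1.79e-10 to 0.25). Mast cell and basophil genes shifted downwards by -0.97. Among 18 measured, 2 fell over all genes and 10 adjusted over the list alone, including Fcer1a, a chain of the IgE receptor, at -2.04 ± 0.26 and the protease Mcpt2 at -2.04 ± 0.25 (camera adjusted p = 5.27e-06; adjusted p = 0.408 with an estimated correlation, range 4.52e-09 to 0.408). Without empty-vector replicate 2 their mean was -0.62 and the call was lost. The dendritic cell and MHC class II list shifted by -0.43 with no member past the threshold by limma, 6 of 16 at an unadjusted p under 0.05, and 1 rising and 2 falling adjusted over the list alone (camera adjusted p = 0.0139; adjusted p = 0.334 with an estimated correlation, range 0.00193 to 0.334). This call was also lost without empty-vector replicate 2 (-0.35) and with the dimmer 25% (-0.55) or 50% (-0.65) of genes left out. Its smallest p-values were those of Tcf4 (1.01 ± 0.18, adjusted p = 0.0564) and Itgax, or CD11c (-2.34 ± 0.45, 0.0666, and 0.0238 with the replicate block, range 0.0238 to 0.240).

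Monocyte and macrophage genes split. Fcgr1, a high-affinity IgG receptor, rose by 2.51 ± 0.27 (adjusted p = 0.0162), while Cd36 and the scavenger receptor Marco (-2.09 ± 0.32, adjusted p = 0.0412, and 0.0514 with the replicate block, range 0.00409 to 0.167) fell. Adjusted over the list alone, 3 of 26 rose and 6 fell. The list mean was -0.33 (camera adjusted p = 0.106; 0.0499 with the replicate block, range 2.27e-05 to 0.7502), and -0.62 without empty-vector replicate 1, where it passed. Among 17 myeloid transcription factors, Egr2 (-1.57 ± 0.17, adjusted p = 0.0183) and Id2, an inhibitor of E proteins (-1.39 ± 0.13, 0.0122), fell. Adjusted over the list alone, 2 rose and 3 fell, and the mean was -0.097 (camera adjusted p = 0.536), or -0.41 without empty-vector replicate 1, where it passed. No eosinophil gene passed by limma, with 3 of 7 at an unadjusted p under 0.05 and 1 rising and 2 falling adjusted over the list alone. Alox15 differed by -1.04 ± 0.26 (adjusted p = 0.129) and Ccr3 by -0.56 ± 0.15 (0.135), and the list mean was -0.33 (camera adjusted p = 0.355). Between the empty-vector arrays themselves, replicate 1 minus replicate 2, the list means differed by -0.70 for mast cell, -0.62 for myeloid transcription factor and -0.59 for macrophage genes. They differed by 0.72 for eosinophil and 0.45 for neutrophil genes.

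Erythroid genes, which include those of heme synthesis and the red cell membrane, averaged -0.81 (camera adjusted p = 0.00226; adjusted p = 0.649 with an estimated correlation, range 7.00e-08 to 0.809). No member passed by limma over all genes or adjusted over the list alone, and 7 of 24 had an unadjusted p under 0.05. The erythroid regulator Gata1 differed by -1.17 ± 0.37 (adjusted p = 0.206) and Rhag by -2.77 ± 0.92 (0.220). Empty-vector replicate 1 was 1.61 higher than replicate 2 over this list, and their mean was -0.0049 without replicate 1, with the call lost, and -1.62 without replicate 2. Megakaryocyte genes shifted by -0.81, and of 16 measured 1 fell, Clec1b, a platelet receptor (-2.68 ± 0.37, adjusted p = 0.0329). Adjusted over the list alone, 1 rose and 9 fell (camera adjusted p = 5.92e-05; adjusted p = 0.408 with an estimated correlation, range 8.11e-08 to 0.408), and the call was lost without empty-vector replicate 2 (-0.74). Of 14 B cell genes, 1 fell over all genes and adjusted over the list alone, the adaptor Blnk (-1.90 ± 0.14, adjusted p = 0.00832), and the list mean was -0.23 (camera adjusted p = 0.355).

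The T and NK cell list had no member past the threshold by limma over all genes or adjusted over the list alone, with 5 of 12 at an unadjusted p under 0.05. Its mean was -0.28 (camera adjusted p = 0.252), Eomes differed by -1.22 ± 0.30 (adjusted p = 0.123) and Gzmb by -0.66 ± 0.19 (0.174). Stromal and endothelial genes had 1 of 15 at an unadjusted p under 0.05 and no call by limma, also adjusted over the list alone. Pdgfrb differed by 2.08 ± 0.46 (adjusted p = 0.0977, and 0.0411 with the replicate block, range 0.0149 to 0.324) and Col1a2 by -0.42 ± 0.20 (0.357), with a list mean of 0.11, a median of -0.075 and a test direction upwards (camera adjusted p = 0.894). Sex-linked genes had no call of either kind by limma and 0 of 5 at an unadjusted p under 0.05. Their mean was -0.045 (camera adjusted p = 0.883), with Kdm5d at -0.16 ± 0.16 and Tsix at -0.035 ± 0.17, or 0.0026 with quantile normalization.

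Within the Hoxa cluster 2 of 9 measured genes rose, over all genes and adjusted over the list alone. These were Hoxa9, whose 2nd probe set differed by 1.19, and Hoxa5 (1.05 ± 0.13, adjusted p = 0.0265). Hoxa7 differed by 0.36 ± 0.17 (adjusted p = 0.360), and Hoxa2 (0.20), Hoxa3 (0.098), Hoxa4 (-0.090), Hoxa10 (0.082), Hoxa11 (-0.12) and Hoxa13 (0.037) did not pass. The list shifted upwards by a mean of 0.55 and a median of 0.098 (camera adjusted p = 0.0162; adjusted p = 0.429 with an estimated correlation, range 0.00524 to 0.429), and its call was lost without empty-vector replicate 2 (0.57) and without shRNA1 replicate 2 (0.51). Hoxa9 missed the threshold without any single one of the 4 shRNA arrays, at adjusted p of 0.0832 and 0.0585 without shRNA1 replicates 1 and 2 and 0.0819 and 0.0778 without shRNA2 replicates 1 and 2 (range 0.00240 to 0.0832).

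Among cohesin subunits and regulators, Stag1, the alternative of Stag2 in the complex, rose by 1.26 ± 0.20 (adjusted p = 0.0454; 0.0565 with the replicate block and 0.0583 without empty-vector replicate 1, range 0.00995 to 0.204). Adjusted over the list alone, 1 of 16 rose and 1, Rad21, fell. The list mean was -0.041, the median 0.021 and the test direction upwards (camera adjusted p = 0.875). Of 25 stem and progenitor cell genes, the receptor Kit fell (-1.61 ± 0.25, adjusted p = 0.0412), and adjusted over the list alone 2 rose and 5 fell. That list averaged -0.19 (camera adjusted p = 0.467). Polycomb group genes, repressors of Hox loci, had no call by limma over all genes or adjusted over the list alone, with 3 of 23 at an unadjusted p under 0.05. Phf1 differed by -1.12 ± 0.27 (adjusted p = 0.116) and Ezh1 by -0.59 ± 0.18 (0.196), and the mean was -0.033 (camera adjusted p = 0.883).

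All 29 measured mitosis genes had positive differences, with a mean of 0.85. Of these, 7 rose over all genes and 12 adjusted over the list alone, among them the kinase Aurkb (1.83 ± 0.17), the cyclin Ccnb2 (1.78 ± 0.17), the kinesin Kif20a (1.67 ± 0.15) and Cdk1 (1.23 ± 0.14), with adjusted p from 0.0121 to 0.0200. The list call (camera adjusted p = 2.29e-12; adjusted p = 0.408 with an estimated correlation, range 1.43e-24 to 0.408) was lost without empty-vector replicate 2, at a mean of 0.31, and the mean was 1.40 without replicate 1. DNA replication genes shifted by 0.38 (camera adjusted p = 0.000318; adjusted p = 0.649 with an estimated correlation, range 1.60e-13 to 0.649). None of 25 passed by limma, 9 had an unadjusted p under 0.05 and 4 rose adjusted over the list alone, and Mcm6 differed by 0.91 ± 0.17 (adjusted p = 0.0669) and Prim1 by 1.11 ± 0.22 (0.0783). Their mean was 0.88 without empty-vector replicate 1 and -0.11, with the call lost, without replicate 2. Myc and nucleolar genes, which serve ribosome assembly, shifted by 0.24 (camera adjusted p = 0.00560; adjusted p = 0.649 with an estimated correlation, range 1.93e-07 to 0.858). No member passed by limma or adjusted over the list alone, with 3 of 22 at an unadjusted p under 0.05, and Srm differed by 0.66 ± 0.15 (adjusted p = 0.102) and Nop16 by 0.76 ± 0.22 (0.164). Their mean was 0.52 without empty-vector replicate 1, and the call was lost without empty-vector replicate 2 (-0.053) and without shRNA1 replicate 1 (0.15). Replicate 1 of the empty vector was above replicate 2 by 1.09 for mitosis, 0.99 for DNA replication and 0.58 for Myc and nucleolar genes.

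Cholesterol synthesis genes shifted by 0.40, and of 15 measured 1 rose over all genes, Fdps, which makes farnesyl diphosphate (1.60 ± 0.21, adjusted p = 0.0286), and 3 adjusted over the list alone (camera adjusted p = 0.00237; adjusted p = 0.408 with an estimated correlation, range 1.27e-05 to 0.408). Their call was lost without empty-vector replicate 2, at 0.29. Hypoxia and glycolysis genes shifted by 0.44, with no call by limma over all genes, 9 of 16 at an unadjusted p under 0.05 and 8 rising adjusted over the list alone (camera adjusted p = 1.03e-05; adjusted p = 0.408 with an estimated correlation, range 4.00e-06 to 0.408). Bnip3 differed by 0.97 ± 0.16 (adjusted p = 0.0516) and the glycolytic enzyme Pgk1 by 0.77 ± 0.14 (0.0572), both past the threshold with an intensity trend.

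Interferon-stimulated genes shifted downwards by a mean of -0.97, and 27 of 29 had negative differences. Of these, 4 fell over all genes and 14 adjusted over the list alone: beside Ifit1 and Rsad2, the named ones are Oasl2 (-2.63 ± 0.28, adjusted p = 0.0154) and Usp18, which removes ISG15 (-2.20 ± 0.32, 0.0365). The list's camera adjusted p was 3.66e-11 (adjusted p = 0.25 with an estimated correlation, range 5.66e-16 to 0.25). The integrated stress response list shifted by -0.62, with 4 of 20 falling over all genes and 9 adjusted over the list alone: Trib3 (-2.73 ± 0.15), the amino acid transporter Slc7a5 (-1.77 ± 0.20), Atf5 (-1.73 ± 0.16) and Vldlr (-1.51 ± 0.22), with adjusted p from 0.00565 to 0.0365 (camera adjusted p = 5.92e-05; adjusted p = 0.323 with an estimated correlation, range 1.60e-06 to 0.323). The p53 target list shifted by -0.41 (camera adjusted p = 0.00178; adjusted p = 0.290 with an estimated correlation, range 0.000149 to 0.290). No member passed by limma, 7 of 22 had an unadjusted p under 0.05 and 2 fell adjusted over the list alone, with the cell cycle inhibitor Cdkn1a at -0.97 ± 0.17 (adjusted p = 0.0553) and Phlda3 at -1.51 ± 0.26 (0.0558, and 0.0339 with the replicate block, range 0.0337 to 0.215). Immediate early and heat shock genes shifted by -0.46, and of 20 measured 1 fell over all genes, Junb (-1.04 ± 0.15, adjusted p = 0.0395, and 0.0514 with the replicate block, range 0.00471 to 0.193), and 6 adjusted over the list alone (camera adjusted p = 0.00146; adjusted p = 0.408 with an estimated correlation, range 7.78e-05 to 0.408). Of 26 inflammatory NF-kB genes the lectin Clec4e rose (1.91 ± 0.31, adjusted p = 0.0463, and 0.0609 with the replicate block, range 0.00416 to 0.1999) and the chemokine Ccl4 fell (-1.04 ± 0.16, 0.0412, and 0.0554 with the block, range 0.0142 to 0.190), and adjusted over the list alone 1 rose and 2 fell. That list had a mean of -0.084, a median of 0.0052 and a test direction upwards (camera adjusted p = 0.883). Without empty-vector replicate 2 the calls of the integrated stress response (-0.55), p53 target (-0.33) and immediate early lists (-0.51) were lost.

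Of the 26 lists, 15 passed camera with the preset correlation. With an estimated one 0 passed and 4 had an unadjusted p under 0.05. By fry 5 passed, which were the neutrophil (adjusted p = 0.0210), dendritic cell, p53 target, interferon-stimulated and integrated stress response lists (0.0226 each). Without empty-vector replicate 2, 4 lists passed: neutrophil at 1.47, erythroid at -1.62, interferon-stimulated at -0.81 and hypoxia and glycolysis genes at 0.31. The 33 list members named above as passing kept their direction with any array left out, and their calls in 32, 33, 4, 14, 1 and 4 cases in the order of arrays used before, Stag1 being the one lost without empty-vector replicate 1. Of the 22 named members that had not passed, 5 passed without empty-vector replicate 1, 17 without replicate 2 and 1 without shRNA1 replicate 2. Since 262 of the 264 called genes had arrays without overlap between shRNA and empty vector, the kept direction of the 33 says little about stability. With the mean of all probe sets of a gene the calls of Stag1, Id2, Clec4e, Fdps and Vldlr were lost and those of Eomes and Bnip3 gained. Quantile normalization ended the calls of Kit, Marco, Clec4e and Junb, and without the dimmer 50% of genes those of Stag1, Kit, Clec4e, Ccl4 and Junb were lost. Tcf4 passed with quantile normalization or median centring, and Phlda3 with centring.

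**Figure D3:**
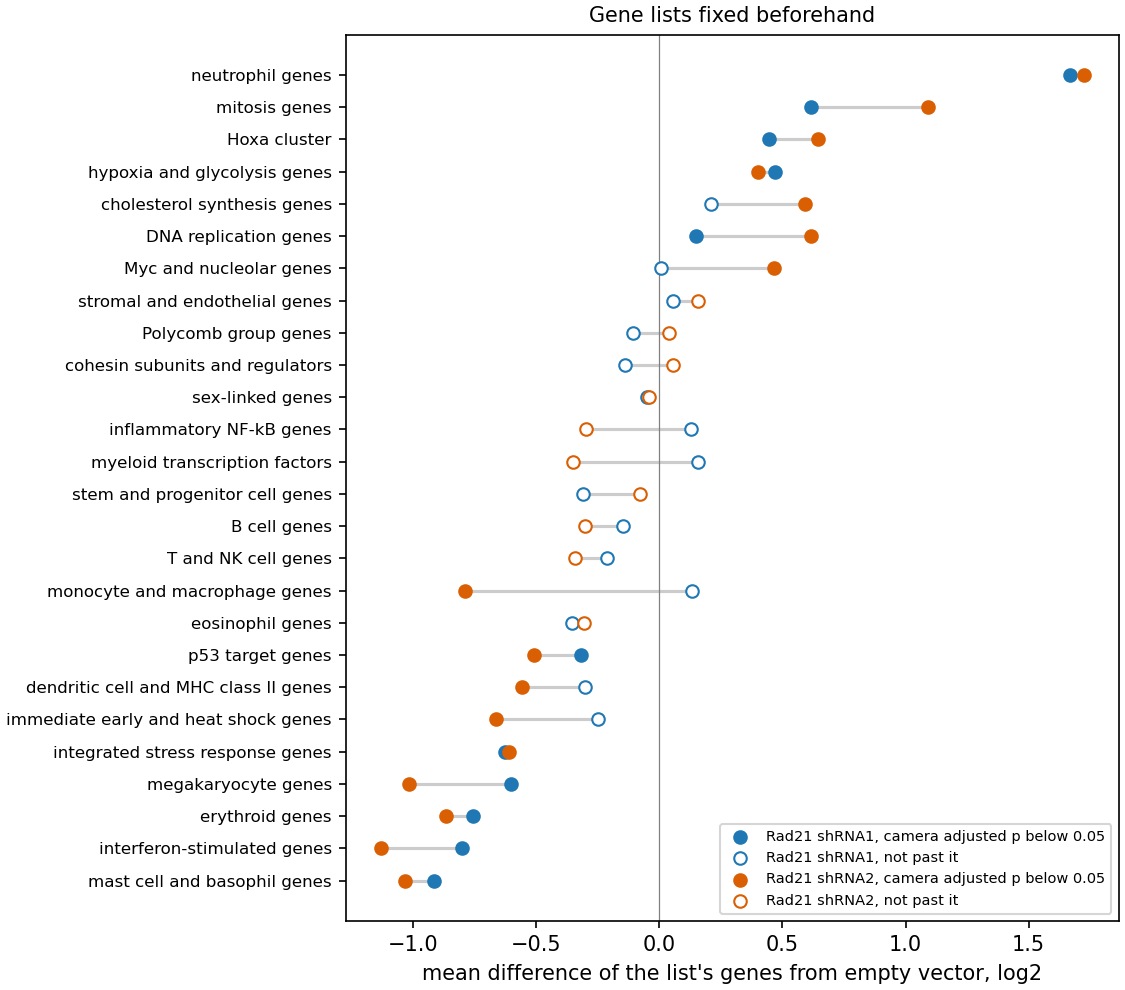
Mean log2 difference from empty vector of each gene list for shRNA1 and for shRNA2, with filled points where camera with the preset correlation gave an adjusted p below 0.05. With an estimated correlation 0 lists passed for either shRNA. Neutrophil genes lie at 1.67 and 1.72, and interferon-stimulated genes at -0.80 and -1.13.

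With shRNA1 alone, Csn2 rose by 5.83 ± 0.27 (adjusted p = 0.00893), followed among genes past the threshold by Elane (4.29 ± 0.25), Prtn3 (4.24 ± 0.39), Myl10 (3.63 ± 0.37) and Tal2 (3.31 ± 0.27), with adjusted p from 0.0162 to 0.0391. Myl10 had an adjusted p of 0.0547 with the replicate block (range 0.00502 to 0.363). The largest falls among genes past the threshold were in Fgfr1 (-3.41 ± 0.25), Mab21l1 (-3.32 ± 0.25), Plet1 (-2.90 ± 0.18), Cdh17 (-2.75 ± 0.28) and Cth, an enzyme of cysteine synthesis (-2.67 ± 0.25), with adjusted p from 0.0171 to 0.0393. Mpo and Rbp4, added after their values were seen, differed by 4.49 ± 0.56 (adjusted p = 0.0582, and 0.0352 with the block) and -4.39 ± 0.90 (0.184, and 0.0379 with the block) without passing. Hoxa9 differed by 2.87 ± 0.37 (adjusted p = 0.0610) and Hoxa5 by 0.71 ± 0.15 (0.194). Hoxa9 passed with the mean of its probe sets, with median centring and with an intensity trend. The other members past the threshold in the lists were Lcn2, a siderophore-binding neutrophil protein (2.07 ± 0.18), Blnk (-1.59 ± 0.16, adjusted p = 0.0393, and 0.0547 with the block, range 0.00622 to 0.425) and Trib3 (-2.58 ± 0.18).

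In total 12 genes rose and 17 fell with shRNA1. The count of 29 was 124 without empty-vector replicate 1 and 2534 without replicate 2. It was 0 by limma without any single one of the 4 shRNA arrays, with 414 and 830 genes at an unadjusted p under 0.05 without shRNA1 replicates 1 and 2 and 807 without either shRNA2 array. With only the groups compared in the fit it was also 0, with 807 at an unadjusted p under 0.05. It was 3 with the dimmer 50% of genes left out, 47 with median centring and 59 with an intensity trend. The 10 genes named by size and the 5 list members kept their direction with any array left out. All 29 called genes had arrays without overlap between the groups, so leaving out an array could not turn a direction. With the mean of all probe sets Mab21l1 (-2.56) and Plet1 (-1.46) missed the threshold and Fgfr1 differed by -2.19, and without the dimmer 50% of genes Prtn3, Myl10 and Lcn2 missed it.

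By camera 11 lists passed with shRNA1 and 1 by fry, and with an estimated correlation 0 passed and 4 had an unadjusted p under 0.05. Neutrophil genes shifted by 1.67 (camera adjusted p = 3.26e-14; adjusted p = 0.227 with an estimated correlation, range 5.10e-16 to 0.227), with 3 of 21 rising over all genes and 10 adjusted over the list alone. Interferon-stimulated genes shifted by -0.80 (8.38e-10; adjusted p = 0.273 with an estimated correlation, range 2.94e-16 to 0.273), and mitosis genes by 0.62 (2.54e-10; adjusted p = 0.503 with an estimated correlation, range 5.11e-27 to 0.503). By limma 0 members of either passed over all genes, with 11 and 10 at an unadjusted p under 0.05, and adjusted over the list alone 6 interferon-stimulated genes fell and 8 mitosis genes rose. Hypoxia and glycolysis (0.47), mast cell (-0.91), integrated stress response (-0.62), megakaryocyte (-0.60), erythroid (-0.76), p53 target (-0.32), Hoxa (0.45) and DNA replication genes (0.15) also passed, with camera adjusted p from 1.63e-07 to 0.0350 and adjusted p from 0.273 to 0.759 with an estimated correlation (range over these lists 4.03e-12 to 0.759). Adjusted over the list alone 4 hypoxia and 2 Hoxa genes rose, and 6 mast cell, 6 integrated stress response and 3 megakaryocyte genes fell. The stromal list had a mean of 0.055 and a median of -0.053, the cholesterol list a mean of 0.21 and a median of -0.013, both with a test direction upwards.

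Without empty-vector replicate 2 calls with shRNA1 were lost for the mast cell (-0.56), megakaryocyte (-0.53), integrated stress response (-0.56), p53 target (-0.24), Hoxa (0.47), mitosis (0.068) and DNA replication lists (-0.35). The macrophage list (0.43) then passed and the erythroid mean was -1.56. Without empty-vector replicate 1 the erythroid call was lost (0.049), the mitosis and DNA replication means were 1.16 and 0.64, and the dendritic cell (-0.38), Myc (0.29) and cholesterol lists (0.32) passed. Without shRNA1 replicate 1 the DNA replication call was lost (-0.040) and the mast cell (-0.59), megakaryocyte (-0.26) and mitosis means (0.41) were smaller, while the stem cell (-0.25), dendritic cell (-0.39) and immediate early lists (-0.31) passed. Without shRNA1 replicate 2 the Hoxa call was lost (0.37), the megakaryocyte and DNA replication means were -0.94 and 0.34, and the NF-kB (0.36) and Myc lists (0.19) passed. Without shRNA2 replicate 1, and likewise without replicate 2, the stem cell (-0.31), dendritic cell (-0.30) and immediate early lists (-0.25) passed, having missed the threshold with all arrays. The DNA replication call was also lost with quantile normalization or with the dimmer 25% or 50% of genes left out, and the immediate early list passed with quantile normalization and without the dimmer 50%. With the replicate block the stem cell list passed at 0.0217 (0.0591 without it, range 0.00717 to 0.401) and the dendritic cell list at 0.0252 (0.0591 without it, range 0.00249 to 0.456).

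With shRNA2 alone, Mpo rose by 6.19 ± 0.56 (73.2-fold, adjusted p = 0.0112), followed by Elane (5.67 ± 0.25), Prtn3 (5.62 ± 0.39), Ms4a3 (4.81 ± 0.70) and Myl10 (4.71 ± 0.37), with adjusted p from 0.00318 to 0.0300. The largest falls were in Rbp4 (-6.41 ± 0.90), Mmp13 (-5.90 ± 0.69), Cdh1 (-5.43 ± 0.56), Plet1 (-4.59 ± 0.18) and Fabp4, a fatty acid carrier of macrophages and adipocytes (-4.26 ± 0.28), with adjusted p from 0.00318 to 0.0282. Hoxa9 rose by 3.71 ± 0.37 (adjusted p = 0.0130), Hoxa5 by 1.39 ± 0.15 (0.0159) and Stag1 by 1.53 ± 0.23 (0.0349). Of the macrophage genes Mertk (-3.30 ± 0.48) and the mannose receptor Mrc1 (-2.64 ± 0.36) fell, as did Cebpb (-1.25 ± 0.16) among the myeloid transcription factors, and Cd34, a progenitor marker, rose by 1.36 ± 0.21.

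In total 109 genes rose and 242 fell with shRNA2. The count of 351 was 1102 without empty-vector replicate 1, 2941 without replicate 2, 120 without shRNA1 replicate 1 and likewise 120 without replicate 2. It was 2 without shRNA2 replicate 1 and 0 by limma without shRNA2 replicate 2, where 1235 genes had an unadjusted p under 0.05. It was 180 with the dimmer 50% of genes left out and 120 with only the groups compared in the fit. The 10 genes named by size kept their direction with any array left out, and their calls in 10, 10, 7, 7, 2 and 0 cases in that order of arrays. The 41 list members taken by the rule kept theirs in 40, 41, 19, 19, 1 and 0 cases, and of the 14 that had not passed 4 passed without empty-vector replicate 1 and 9 without replicate 2. All 351 called genes had arrays without overlap between the groups, so leaving out an array could not turn their direction. With the mean of all probe sets Plet1 differed by -2.36, and Stag1 missed the threshold. Pdgfrb differed by 2.83 ± 0.53 (adjusted p = 0.0569, and 0.0222 with the replicate block, range 0.00842 to 0.342).

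By camera 16 lists passed with shRNA2 and 5 by fry, and with an estimated correlation 0 passed and 3 had an unadjusted p under 0.05. These were the 15 of the joint comparison and the macrophage list, which shifted by -0.79 (camera adjusted p = 0.000332; adjusted p = 0.412 with an estimated correlation, range 7.91e-08 to 0.412), with 1 of 26 rising and 6 falling over all genes and 2 rising and 13 falling adjusted over the list alone. Mitosis genes shifted by 1.09 (3.44e-13; adjusted p = 0.391 with an estimated correlation, range 2.28e-22 to 0.391), with 9 of 29 rising over all genes and 14 adjusted over the list alone. Neutrophil (1.72), interferon-stimulated (-1.13), megakaryocyte (-1.02), mast cell (-1.03), DNA replication (0.62), Myc (0.46), cholesterol (0.59), immediate early (-0.66), hypoxia (0.40), integrated stress response (-0.61), p53 target (-0.51), erythroid (-0.86), dendritic cell (-0.56) and Hoxa genes (0.64) had camera adjusted p from 1.37e-11 to 0.0182 and adjusted p from 0.278 to 0.644 with an estimated correlation (range over these lists 5.27e-15 to 0.957). Over all genes 7 neutrophil genes rose and adjusted over the list alone 10 rose and 2 fell, while 4 interferon-stimulated genes fell over all genes and 15 adjusted over the list alone. The stem cell list had a mean of -0.079, a median of -0.033 and a test direction upwards (camera adjusted p = 0.952).

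Without empty-vector replicate 2 calls with shRNA2 were lost for the macrophage (-0.49), mast cell (-0.68), dendritic cell (-0.48), DNA replication (0.12), p53 target (-0.43), Myc (0.18), cholesterol (0.48), integrated stress response (-0.54) and Hoxa lists (0.67), and the mitosis and erythroid means were 0.55 and -1.67. Without empty-vector replicate 1 the erythroid call was lost (-0.059), the mitosis, DNA replication and Myc means were 1.64, 1.11 and 0.75, and the myeloid transcription factor list (-0.66) passed. Without shRNA2 replicate 2 the erythroid (-0.69) and Hoxa calls (0.59) were lost, and without shRNA2 replicate 1 the NF-kB list (-0.47) passed. The myeloid transcription factor list also passed with the mean of all probe sets (-0.32) and without the dimmer 50% of genes (-0.31), where the dendritic cell mean was -0.90.

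Of the genes called with each shRNA, 12 rose and 17 fell with both, and 0 were called in opposite directions by limma. With the replicate block 23 genes were called with both, 16 of them among these 29. Among the genes shared were Elane, Prtn3, Csn2, Tal2, Plet1 and Trib3. Independent lists of these lengths would share 0.105 rises and 0.332 falls, and unchanged groups simulated against the same controls shared 0 genes with 1 spread and 0.03 with a spread per group. None of these simulated values includes the correlation of 0.578 between the deviations of same-numbered arrays of the 2 shRNAs. Over 12393 genes, which are not independent replicates, Pearson's r was 0.859 and Spearman's rho 0.805, against a simulated r of 0.4998 with 1 spread and 0.828 with a spread per group. The covariance was 0.236 against 0.0343 and 0.0726, differences of 0.201 and 0.163, and signs matched in 80.3% of genes against 66.7% and 81.0%. With each shRNA set against a different empty-vector array r was 0.259 or 0.487 and the covariance 0.107 or 0.158. Both covariances lie below the differences of 0.201 and 0.163, so part of that excess comes from the shared controls. The 2 controls cannot be split into sets of 2, so these values each rest on single control arrays.

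**Figure D4:**
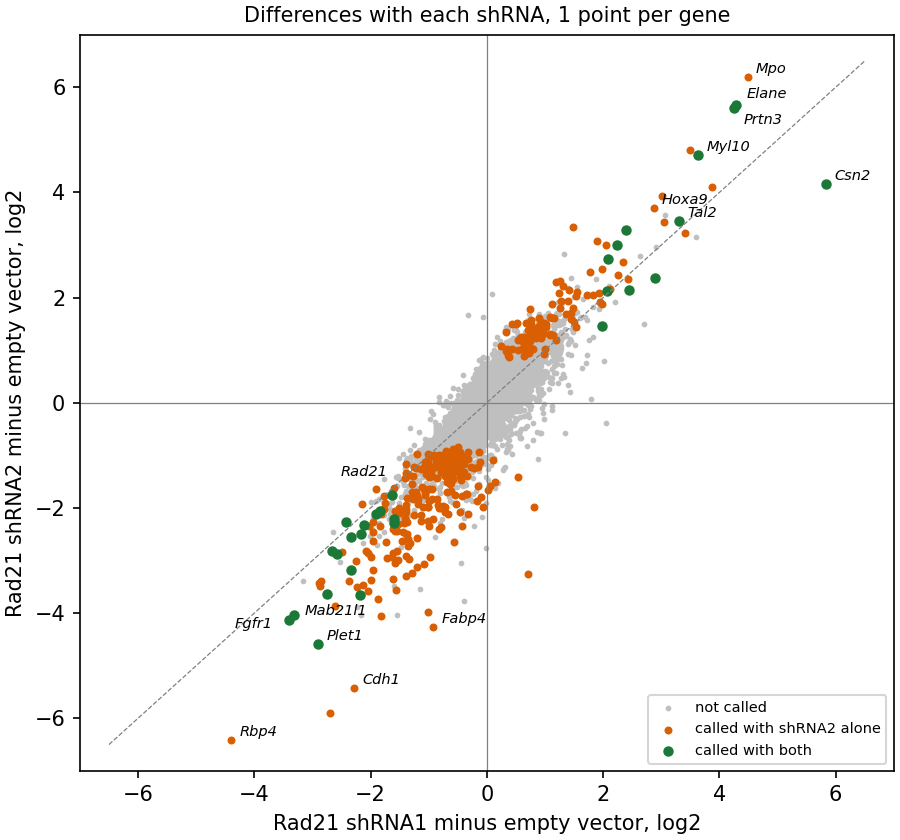
Log2 difference from empty vector with shRNA1 (x axis) and shRNA2 (y axis) for 12393 genes, grey where not called, orange where called with shRNA2 alone and green where called with both. The 29 genes called with both lie in the 2 quadrants of equal sign.

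The direct comparison of the shRNAs, shRNA1 minus shRNA2, gave 0 genes by limma past the threshold and 606 at an unadjusted p under 0.05, and the smallest adjusted p was 0.204. Rad21 differed by 0.077 ± 0.30 between them (95% interval -0.65 to 0.81), and by -0.17 without shRNA1 replicate 1 and -0.12 without shRNA2 replicate 2. The genes with the smallest p in each direction, none of which passed, were Fabp4 (3.34 ± 0.28), the scavenger receptor Colec12 (2.79 ± 0.28), Olfm1 (1.91 ± 0.19), Plet1 (1.69 ± 0.18) and the cytokine Il1b (1.5 ± 0.17) on the higher side, and Nhsl1 (-0.99 ± 0.17), Elane (-1.38 ± 0.25), Muc13 (-0.82 ± 0.15), Crisp3 (-1.97 ± 0.38) and Tex2 (-1.003 ± 0.20) on the lower side. With only these 2 groups in the fit 44 genes passed, all 44 higher with shRNA1, and 6 of the 52 list members taken by the rule did so. Leaving out either empty-vector array repeats this calculation, because the lone array left in that group adds nothing to the estimated spread. Without shRNA1 replicate 1 or 2, or shRNA2 replicate 1 or 2, 0 passed by limma, with 484, 233, 280 and 284 genes at an unadjusted p under 0.05.

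Of the lists, 12 passed camera. With an estimated correlation and by fry 0 passed, with 3 and 1 at an unadjusted p under 0.05. Macrophage genes were higher with shRNA1 by a mean of 0.92, with 24 of 26 differences positive and 11 higher and 1 lower adjusted over the list alone (camera adjusted p = 6.68e-17; adjusted p = 0.328 with an estimated correlation, range 1.69e-20 to 0.328), and Lpl (1.65 ± 0.20) and Msr1 (1.68 ± 0.20) had the smallest p. All 29 mitosis, all 25 DNA replication and all 15 cholesterol synthesis genes had negative differences, with means of -0.48, -0.47 and -0.38 and no call adjusted over the list alone (camera adjusted p = 3.80e-09, 7.63e-07 and 3.92e-05; adjusted p = 0.444, 0.444 and 0.328 with an estimated correlation, ranges 9.84e-13 to 0.464, 2.76e-10 to 0.528 and 4.00e-07 to 0.328). Myc and nucleolar genes averaged -0.46, stem cell genes -0.23 and cohesin genes -0.20. Myeloid transcription factors averaged 0.50, with 5 higher adjusted over the list alone, NF-kB genes 0.43, megakaryocyte genes 0.41, immediate early genes 0.41 and interferon-stimulated genes 0.33. These 8 lists had camera adjusted p from 2.35e-08 to 0.0248, and adjusted p from 0.328 to 0.444 with an estimated correlation (range over these lists 6.60e-11 to 0.832). Mean, median and test direction differed in sign for the neutrophil (-0.053, 0.051, upwards), mast cell (0.12, -0.16, upwards), B cell (0.15, -0.00010, upwards) and integrated stress response lists (-0.012, -0.023, upwards).

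Without shRNA1 replicate 2 the calls between the shRNAs were lost for the cohesin (-0.14) and megakaryocyte lists (0.072) and the DNA replication, mitosis, Myc, interferon-stimulated and NF-kB means were -0.28, -0.27, -0.28, 0.21 and 0.66, while the Hoxa (-0.27), dendritic cell (0.35) and p53 target lists (0.20) passed. Without shRNA2 replicate 1 the cohesin call was lost (-0.21), and the Hoxa (-0.25), dendritic cell (0.31), p53 target (0.24) and integrated stress response lists (0.083) passed. Without shRNA1 replicate 1 the stem cell (-0.18) and NF-kB calls (0.20) were lost, the megakaryocyte mean was 0.75, and the mast cell (0.44) and T and NK cell lists (0.24) passed. Without shRNA2 replicate 2 the NF-kB call was lost (0.25) and the cholesterol mean was -0.24. The Polycomb list (-0.14) passed without either empty-vector array. With the mean of all probe sets the cohesin call was lost and the Hoxa, Polycomb and p53 target lists passed. With the replicate block the dendritic cell list (0.26, range 0.00111 to 0.518) and the p53 target list (0.19, range 0.00570 to 0.481) passed, both at 0.0122, as they did with median centring and without the dimmer 25% or 50% of genes, and the Polycomb list passed without the dimmer 25%.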

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

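The tests of the control probe sets and of the erythroid list on empty-vector replicate 1, and those of the Rad21 level and RNA quality behind the macrophage difference, were chosen only after the results were seen.

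Empty-vector replicate 1 drew attention through control probe sets that enter no comparison of genes. Its Gapdh 3′ minus 5′ gap was 2.42, its Actb gap 2.55 and its added poly-A control RNAs averaged 10.58 on the log2 scale, each above all 5 other arrays. Partly degraded RNA (Gapdh gap 2.405 above the highest other array) and a smaller amount of RNA (poly-A minus hybridization controls 1.165 above the highest other) are candidate explanations, but these values restate what drew attention and are no independent tests. A culture with more erythroid cells is a further one, also without an independent test: the erythroid median was 1.22 higher on replicate 1 than on replicate 2, at percentile 100 of 10000 lists matched on expression, whose medians ran from -0.51 to 0.52, and 23 of 24 genes were higher. The first 2 rest on control probe sets and the last on erythroid genes, so they concern different values. Which of the 3 hold cannot be told, since no value in the tables excludes one and they can hold together. No biological explanation from the design was tested, because both arrays belong to the same group.

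Of the erythroid genes with the highest means over the other 5 arrays, Tfrc stood at 11.88 on replicate 1 and 10.54 on replicate 2, Car2 at 11.76 and 10.88, and Nfe2 at 10.96 and 10.33. The largest gaps of the list were in Tspan33, at 9.875 and 5.913, and Slc4a1, at 11.706 and 8.136. The 4 bright probe sets listed under several globin genes were 0.62 to 1.85 higher on replicate 1, while Hba-a2 on its own dim probe set was lower, at 4.56 against 5.26. No gene of this list stands in another list (0 of 24), and 10 lay above the array median on all 5 other arrays, which without a detection measure does not settle how many the other cultures express. The depletion of lineage-positive marrow before culture would remove cells that already carried erythroid surface markers, but not those formed during the culture. Genes of other lists also differed between these 2 arrays. Neutrophil genes averaged 0.45 higher on replicate 1, with Camp at 11.26 against 7.49 but Mmp8 lower, at 9.73 against 11.20.

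Monocyte and macrophage genes were higher with shRNA1 than with shRNA2 by a mean of 0.92, by a direct test of the difference (camera adjusted p = 6.68e-17; adjusted p = 0.328 with an estimated correlation, range 1.69e-20 to 0.328). Unequal RNA quality is argued against by the control gaps, which differed between the shRNAs by -0.077 for Actb and 0 for Gapdh. A deeper Rad21 knockdown with shRNA2 may contribute and cannot be told apart from other effects of either shRNA: Rad21 differed by 0.0775, but with 2 arrays per group the 95% interval of -0.654 to 0.809 holds both no difference and a large one. Effects of an shRNA on other transcripts stay open and were not tested.

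The other lists that differed between the shRNAs, shRNA1 minus shRNA2, were higher with shRNA1 for myeloid transcription factors (0.50), inflammatory NF-kB (0.43), megakaryocyte (0.41), immediate early and heat shock (0.41) and interferon-stimulated genes (0.33). They were lower with shRNA1 for mitosis (-0.48), DNA replication (-0.47), Myc and nucleolar (-0.46), cholesterol synthesis (-0.38), stem and progenitor cell (-0.23) and cohesin genes (-0.20). These calls rest on camera's preset correlation: with an estimated one the adjusted p of these 11 lists ran from 0.328 to 0.444.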

How the results depend on the processing

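No setting in this part was chosen after the results were seen, but the move of 0.1 that counts as a change of a correlation was set with the values against different empty-vector arrays known.

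Over the named genes, alternatives left the call as it was in 3362 cases, ended it in 432, brought it about in 131 and turned the direction of a called gene in 0. A large part of the 3362 cases are genes without a call in either fit, which show no stability, while all 432 losses fell on called genes. With an array left out, most called genes could not turn direction, as their arrays did not overlap. The sign changed in 22 cases without a call in either fit, all in sex-linked genes, uncalled Hoxa genes and the Rad21 difference between the shRNAs. For the lists 1230 cases left the call as it was, 140 ended it, 49 brought it about and 5 turned the test direction, all 5 with an empty-vector array left out. The 1230 cases likewise include lists without a call in either fit. Counts of called genes stayed within 1.5 times in 31 cases and moved further in 28, where 12 of the 31 are counts between the shRNAs that were 0 in both fits and show no stability. Counts of lists did so in 45 and 11. With the dimmer 50% of genes left out, 113 genes passed for both shRNAs together, 3 for shRNA1 and 180 for shRNA2, with fewer genes tested. For shRNA1, 47 passed with median centring and 59 with an intensity trend, and the cause was not tested. With only the groups compared in the fit, where fewer arrays estimate the spread, 0 passed by limma for shRNA1 (807 at an unadjusted p under 0.05), 120 for shRNA2 and 44 between the shRNAs. Between the shRNAs this takes the empty-vector arrays, which lay furthest apart, out of the spread. Fits without an array of the group not compared repeat these counts and are tallied again in the cases above. The joint count was 215 with the dimmest 25% left out, 231 with the mean of all probe sets, 206 with quantile normalization, 275 with centring, 256 with a trend, 249 with robust settings and 288 with the replicate block, 213 of the last shared with the reported 264. With 1 array left out, the counts ran from 3 to 3121 for both shRNAs, from 0 to 2534 for shRNA1, from 0 to 2941 for shRNA2 and from 0 to 44 between the shRNAs. At these counts of 0 by limma, 414 to 830 genes for shRNA1, 1235 for shRNA2 and 233 to 484 between the shRNAs had an unadjusted p under 0.05. Rad21 ran from -1.80 to -1.15, and the replicate block, at -1.47, brought it past the threshold (adjusted p = 0.0166, range 0.00721 to 0.203). For both shRNAs together 4 to 16 lists passed with 1 array left out, 0 with an estimated correlation (4 at an unadjusted p under 0.05) and 5 by fry. List means ran from -1.62 to -0.0049 for erythroid, from -0.11 to 0.88 for DNA replication and from -0.053 to 0.52 for Myc genes, and with shRNA1 from -1.56 to 0.049 for erythroid and from -0.35 to 0.64 for DNA replication genes. The correlation of the shRNA effects lay between 0.769 and 0.900 with 1 array left out. It was 0.259 and 0.487 against different empty-vector arrays, where by construction the effects share no control. The replicate block gained 8 calls of named genes and lost 11, gained 5 calls of lists, and changed no other call of a named gene or list. Among genes not named, calls changed too: over all genes it kept 16 of the 29 calls for shRNA1 and 317 of the 351 for shRNA2. The intensity trend and robust settings were not run for the lists, and lists left with under 5 members gave no value: the Hoxa and sex-linked lists without the dimmest 25% of genes, and also the T and NK cell, eosinophil, B cell and stromal lists without the dimmer 50%. The deposited values carry no background or detection measure, so which dim genes lay above background cannot be told, and differences of dim genes are compressed.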

Other observations

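Both tests of the neutrophil rise were chosen only after the result was seen, and the STAT5 and PPAR-gamma tests were written after Csn2, Fabp4, Cd36 and Lpl had drawn attention but before the values of their lists were computed.

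Among the 29 genes called with both shRNAs are several outside the lists, chosen here after their values were seen. Cdkn2a, which encodes cell cycle inhibitors of the Rb and p53 pathways, fell by 2.43 ± 0.16 with shRNA1 and by 2.27 ± 0.16 with shRNA2 (limma adjusted p = 0.0171 and 0.00787), and averaged 8.29 on the empty-vector arrays. Ccnd1, or cyclin D1, fell by 1.84 ± 0.19 and 2.06 ± 0.19 (adjusted p = 0.0393 and 0.0117), and the growth factor gene Pdgfa fell by 1.61 ± 0.17 and 2.29 ± 0.17 (0.0423 and 0.00787). Plac8 rose by 2.39 ± 0.26 and 3.28 ± 0.26, the fatty acid receptor Gpr84 by 2.24 ± 0.21 and 3.01 ± 0.21 and F13a1, a coagulation factor subunit made by monocytes and platelets, by 2.45 ± 0.22 and 2.15 ± 0.22, with adjusted p from 0.00787 to 0.0442. In these 6 genes all 4 shRNA arrays lay beyond both empty-vector arrays, as they did in all 29 genes called with both shRNAs. Their calls with shRNA1 were lost without any single one of the 4 shRNA arrays, at adjusted p from 0.0976 to 0.458, and those with shRNA2 without either shRNA2 array, at 0.0762 to 0.144. With the replicate block the shRNA1 calls of Ccnd1 and Pdgfa (0.0547 each, ranges 0.00681 to 0.371 and 0.00603 to 0.458), Plac8 (0.0559, range 0.00675 to 0.363) and Gpr84 (0.0527, range 0.00603 to 0.363) were lost. Without the dimmer 50% of genes those of Plac8, Gpr84 and F13a1 were lost, without the dimmest 25% that of Pdgfa, with quantile normalization that of Plac8 and with the mean of all probe sets that of Ccnd1.

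The rise of the neutrophil list was uneven. The quality of empty-vector replicate 1 is argued against as its cause, since the mean was 1.92 without that array and 1.70 with all arrays. Among genes with an empty-vector mean below 10, a limit set after a first run over all 5 and 16 genes had given a gap of 3.53, the 4 primary granule genes differed by a mean of 4.85 and the 8 genes of later stages by 0.76, of which 3 were lower, a gap of 4.09. The mean of the later genes was 1.03 without empty-vector replicate 1 and 0.49 without replicate 2, with gaps of 4.24 and 3.94. A larger share of neutrophil-lineage cells and a shift towards early granulocyte precursors may both contribute and cannot be told apart, because the 4 genes were already known as the list's largest rises and the later genes were not shown to come from neutrophils alone.

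Csn2 is a known target of the transcription factor STAT5, and the hypothesis that other STAT5 targets rose with it was left undecided. The 13 measured of 15 listed targets without Csn2 had a mean difference of -0.325 with a standard error over genes of 0.334, 4 positive and 9 negative (camera p = 0.117, and p = 0.309 with an estimated correlation). A mean at or below 0 had been written down beforehand as the outcome against the hypothesis, and the mean met it. The mean lies within 1 standard error of 0, however, a condition that was not part of that prediction. For this reason the hypothesis was left undecided. Of the 13 genes Il2ra, chosen after its values were seen, rose by 2.26 ± 0.27 (limma adjusted p = 0.0228). This call was lost without shRNA1 replicate 1 or 2 and without shRNA2 replicate 1. None of the 9 negative differences passed, the largest being Igf1 (-2.35 ± 0.58, limma adjusted p = 0.122) and Bcl2l1 (-1.84 ± 0.34, 0.0630).

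Fabp4 and Cd36 are known targets of the nuclear receptor PPAR-gamma, and the hypothesis that other targets fell with them was also left undecided. The 13 measured of 15 listed targets without Fabp4, Cd36 and Lpl had a mean difference of -0.213 with a standard error of 0.166 and a median of 0.003, with 7 positive and 6 negative differences (camera p = 0.469, and p = 0.499 with an estimated correlation). The largest differences were falls, in Pparg (-1.72 ± 0.39, limma adjusted p = 0.103) and Abcg1 (-1.15 ± 0.25, 0.0885), neither past the threshold. The largest of the 7 positive differences was 0.33, in Acaa2. Only the mean of both shRNAs was tested for this list, although Fabp4 differed by 3.34 between them. The list decides neither for nor against the hypothesis.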
